A study of Homo sapiens with 6 samples.

How the data were processed

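Messenger RNA of HT29 cells, an established line from a human colorectal adenocarcinoma, was sequenced after 24 h with YM155 or with DMSO, the solvent control. Each treatment had 3 libraries, and the group and replicate number of each library were taken from its labels. The labels state that samples were run in triplicate and not whether these came from separate cultures, so the p-values measure the spread between these samples, which may be technical. Per the labels' protocols, total RNA was extracted with a column kit and libraries were made with a stranded mRNA kit.

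The authors deposited a table of FPKM values (fragments per kilobase of transcript, scaled to library size) per library, with 26255 rows named by gene symbol. How library size was taken is not stated, so the values may already be scaled between libraries. Their median-of-ratios factors lay between 0.987 and 1.016. Per the submitters' processing notes, the tools were TopHat2 2.1.1, Bowtie2 2.3.5.1, SAMtools 1.2, Cufflinks 2.2.1 and Cuffdiff, and the genome build was hg19. Their settings, the gene annotation, the read totals and whether strand was used in quantification are not given in the sources used here. Overlapping and antisense genes are therefore uncertain, and so are genes with near-identical copies, such as the metallothioneins, the AKR1C genes, KRT17 and the FAM25 genes. Positions in the genome were not used here, since the annotation at hand was of another build. It served only for gene class, gene length and older symbols (RefSeq, assembly GRCh38.p14; 98.8% of tested genes matched by symbol) and for the read estimate below (GENCODE release 29).

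FPKM values divide by depth and by transcript length, so they hold no counts. The smallest steps between low values were used to estimate what 1 read was worth in each library. That worth relative to DMSO replicate 1 was 0.997 and 1.12 in DMSO replicates 2 and 3, and 1.78, 1.53 and 1.75 in YM155 replicates 1 to 3. With single-transcript genes and an assumed fragment length of 200 bases, this corresponds to about 27.2, 27.3 and 24.4 M effective reads in the DMSO libraries and 15.2, 17.8 and 15.5 M in the YM155 libraries. On that scale 61.1% to 68.2% of low values lay within 0.1 read of a whole number, against 20% for values spread evenly. The scale had been chosen to put low values of the same genes on whole reads, so 20% is not its chance level. Since many low values were not near a whole number, genes were tested without conversion to reads and without a count model. Only to compare replicates were values of single-transcript genes converted to reads on that scale. Replicates of a group then differed by more than Poisson sampling in every pair (chi-square per degree of freedom of 1.28 to 3.60), so none were treated as the same library. Part of that excess may come from the conversion.

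Genes with an FPKM of at least 1 in at least 3 of the 6 libraries were tested (12035 genes). Values were taken as log2(FPKM + 1) and compared between the groups with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend, two-sided), with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. A log2 fold change is on this scale, which understates the change of scarce transcripts. Folds are ratios of mean FPKM. No replicate block entered the fit. Of 46 gene lists fixed before the data were examined, the 41 with at least 4 tested members were tested with limma's camera (preset inter-gene correlation 0.01), which compares a list with all other genes, and again with the correlation estimated from the data. The same lists were tested with fry, which asks whether the genes of a list move on balance in the same direction without comparing them with other genes.

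The rule for naming genes was also fixed before the data were examined. It took BIRC5, the 10 largest rises and the 10 largest falls among genes past the threshold with a mean of at least 5 FPKM in the higher group and no overlap between groups, up to 4 members with the lowest p of each list described, the most abundant member that did not pass, and every tested member of lists with at most 8 members. Which 23 lists are described in full, and so which members the rule took, was settled after the data were seen, when 2 lists (absorptive enterocyte and NF-kB) were left out, but every tested list has its counts and test printed. Not every gene that the rule took is printed. Any other gene in the text was chosen after its values were seen. Alternatives for each choice were a pseudocount of 0.1 or 0.5, no filter, a mean FPKM of at least 5, median-of-ratios, upper-quartile and quantile scaling, rescaling to a common sum, eBayes without trend or robust, array quality weights, a replicate block, leaving out each library, camera on ranks, and a threshold of 0.01. Leaving out small RNA rows and removing the abundance trend by cyclic loess were added after seeing the data, as were the scalings of the abundance deciles and the estimated correlation for families of genes sharing a symbol stem.

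The test was checked on simulated data for this comparison, with 200 of 12035 genes changed. It called 32%, 70%, 96% and 100% of the genes changed by 0.25, 0.5, 1 and 2 on the log2 scale, and 3 of its 152 calls were unchanged genes. None of 20 random lists of unchanged genes was called by camera. Noise was drawn independently for each gene and few genes were changed. The check therefore does not show how often camera calls lists falsely in these data. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the read estimate and the plots.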

Results

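The transcriptomes of HT29 colorectal adenocarcinoma cells treated for 24 h with YM155, a small molecule described as a suppressor of survivin (BIRC5) expression, or with DMSO were compared, with 3 libraries in each group. Each library listed an FPKM for 26255 genes, of which 19085 were above 0 in any library. The files give no read totals. The steps of low FPKM values put the DMSO libraries at about 24.4 to 27.3 M effective reads and the YM155 libraries at about 15.2 to 17.8 M, so low levels were measured less precisely with YM155. FPKM values summed to 547222 ± 13938 per DMSO library and 684616 ± 9919 per YM155 library (SD, n = 3), a ratio of 1.25. Genes at 100 FPKM or more numbered 641 ± 7.57 with DMSO and 921 ± 5.13 with YM155. Pearson correlations of log2 values across genes, which are not independent replicates, were 0.992 to 0.994 within groups and 0.860 to 0.878 between groups, and the first principal component held 93.7% of the variance.

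The comparison asked how 24 h of YM155 changed messenger RNA levels. BIRC5, the gene of the inhibitor of apoptosis protein survivin, fell 3.42-fold, from 21.8 ± 0.940 to 6.36 ± 0.671 FPKM (SD, n = 3; log2 fold change -1.63, SE 0.07, adjusted p = 6.8e-08). Its level was 21.6, 20.98 and 22.8 FPKM in the DMSO libraries and 7.13, 6.07 and 5.89 FPKM in the YM155 libraries. BIRC5 is itself 1 of the 40 genes of G2/M and mitosis below, of which 36 fell and 3 rose (median log2 fold change -1.06). Members such as KIF20A (-2.47), CENPF (-1.77) and TOP2A (-1.77) fell further. A fall of BIRC5 apart from these genes was not tested. Of 27 genes of the integrated stress response 25 rose and 1 fell, and of 24 NRF2 and oxidative stress genes all rose, among them TRIB3, a pseudokinase induced by ATF4 and CHOP (24.8-fold, from 40.5 ± 3.89 to 1006 ± 23.9 FPKM), and SRXN1, the sulfiredoxin gene of the NRF2 response (25.9-fold, from 16.98 ± 0.0455 to 439.7 ± 9.56 FPKM). Of 40 genes of S phase and DNA replication 35 fell and 3 rose, and of 40 genes of G2/M and mitosis 36 fell and 3 rose, the falls including MCM6 of the replicative helicase (4.55-fold, from 31.02 ± 0.462 to 6.81 ± 0.308 FPKM) and KIF20A, a kinesin of cytokinesis (9.36-fold, from 11.1 ± 0.820 to 1.19 ± 0.212 FPKM). These 4 lists were called by camera with its preset correlation and not with an estimated correlation (adjusted p of 0.18, 0.19, 0.29 and 0.33). The goblet cell gene SPINK4 fell 8.60-fold and the stem cell gene LGR5 8.10-fold. The goblet list was called by camera (adjusted p = 0.041). Its call ended with upper-quartile and sum scaling, without a filter and with an estimated correlation. The stem cell list was not called (adjusted p = 0.12 by camera).

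**Figure D1:**
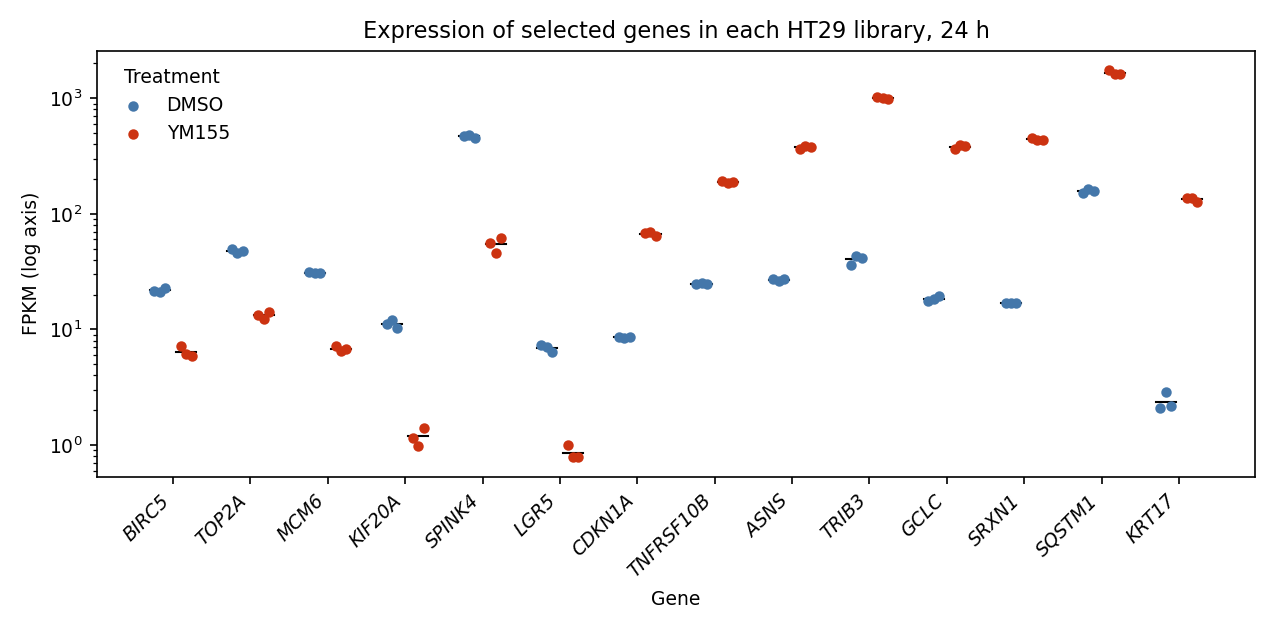
FPKM on a log axis of 14 named genes in each of the 6 libraries (blue, DMSO; red, YM155; points are libraries and bars are means of 3). No gene shown had overlapping groups, and BIRC5 lay between 20.98 and 22.8 FPKM with DMSO and between 5.89 and 7.13 FPKM with YM155.

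Of 12035 tested genes, 5251 rose and 4940 fell by limma at an adjusted p under 0.05, and 1844 did not pass. The groups did not overlap for 85.9% of genes, against 10% by chance. A log2 fold change of at least 1 on the log2(FPKM + 1) scale was seen for 1918 of the genes that rose, and of at most -1 for 1416 of those that fell. These counts were 1179 and 2401 after upper-quartile scaling, 1305 and 2666 after rescaling to a common sum, and 2204 and 2155 with a pseudocount of 0.1. The split of calls depended on scaling: 51.5% of calls were higher with the deposited values, against 36.4% (3767 higher, 6584 lower) after upper-quartile scaling and 37.4% (3828 higher, 6418 lower) after rescaling to a common sum. Those scalings moved the median log2 fold change of all genes by -0.31 and -0.30, and quantile normalization moved it by -0.11. The direction of small changes therefore depended on the scaling. The camera test compares a list with all other genes, but the counts and medians of list members are on the deposited scale and depend on it too. The change also followed transcript abundance: the median log2 fold change was -0.55 in the scarcest decile of tested genes and 0.34 in the decile with a median of 46.3 FPKM. Upper-quartile scaling put these medians at -0.73 and -0.0025, and sum scaling at -0.88 and 0.0232.

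**Figure D2:**
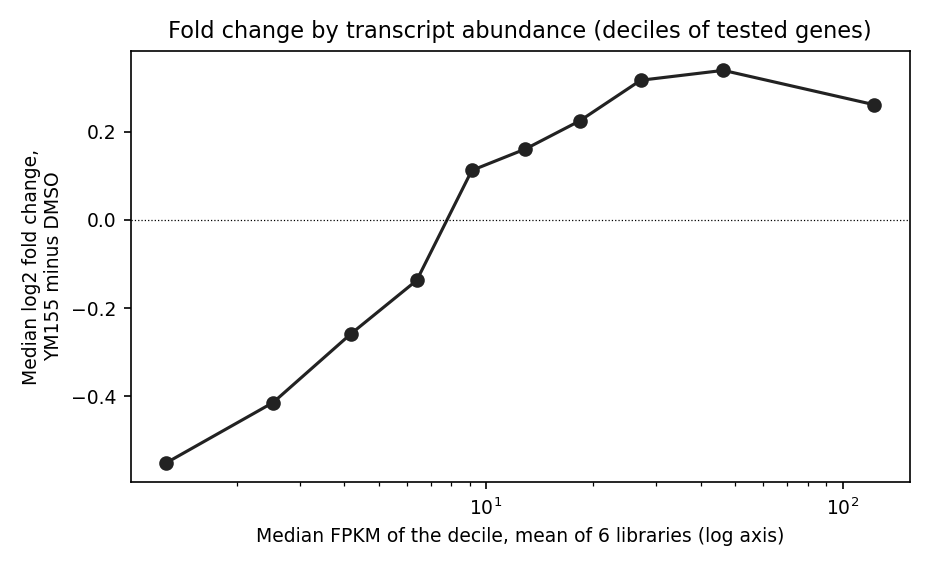
Median log2 fold change (YM155 minus DMSO, on the log2(FPKM + 1) scale) of each decile of the tested genes, against the decile's median FPKM over the 6 libraries on a log axis. The medians run from -0.55 in the scarcest decile to 0.34 in the next to last and 0.26 in the most abundant.

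The largest rise was that of DHRS9, a short-chain dehydrogenase of retinoid metabolism, from 0.467 ± 0.159 to 126 ± 1.91 FPKM (log2 fold change 6.44, SE 0.08, adjusted p = 8.4e-11). DUSP5, a phosphatase of nuclear ERK, rose 65.3-fold, from 7.95 ± 0.156 to 519 ± 13.6 FPKM, and KRT17, a keratin of stressed and basal epithelium, rose 56.2-fold. The netrin receptor gene UNC5B rose 87.4-fold and FAM25A rose 68.7-fold, both from under 1 FPKM. AKR1C1, OSGIN1 and FEM1C rose 40.1-fold, 39.5-fold and 28.1-fold. Reads of AKR1C1, KRT17 and FAM25A can be shared with near-identical genes or pseudogenes, so their levels are uncertain.

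Among the largest falls were GABRP, a GABA type A receptor subunit, 11.1-fold lower (log2 fold change -3.40, SE 0.08, adjusted p = 1.9e-09), and the annexin gene ANXA13, from 134 ± 2.03 to 12.8 ± 1.80 FPKM. The amino acid transporter gene SLC38A11 fell 17.4-fold, the sialyltransferase gene ST6GALNAC1 12.3-fold, the long non-coding RNA LINC00261 12.3-fold and the Notch pathway factor HES6 9.30-fold. The rule also took 4 rows of small RNAs, which FPKM measures poorly because of their length. SNORA45A was listed at 11.1, 38.7 and 12.3 FPKM with DMSO, SNORA80B at 14.2, 4.70 and 10.5, and SNORA68 at 5.11, 5.09 and 17.1, and all were listed at 0 in the 3 YM155 libraries. MIR671 was at 21.7, 44.3 and 26.6 FPKM with DMSO and at 0, 7.53 and 0 with YM155. With small RNA rows left out, which was done after seeing the data, the next falls were those of RAB26 (10.3-fold), SPINK4, LOC101927318 (13.1-fold) and ID2, an inhibitor of differentiation factors (9.27-fold).

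Of the 41 gene lists tested, camera called 7 higher and 5 lower. With the correlation estimated from the data camera called 0 (lowest adjusted p = 0.18, and 7 at an unadjusted p under 0.05). A higher correlation does not account for this in every list. Epithelial junctions and ribosome biogenesis had estimated correlations of -0.0022 and -0.0150, under the preset 0.01, yet their adjusted p rose to 0.18 and 0.19. A call lost in this setting therefore does not by itself show that correlation between genes accounts for the call. The fry test called 38 lists on balance and 41 in either direction. With 10191 of 12035 genes past the threshold, these fry counts do not set the lists apart from other genes. In 7 of the 9 splits of the libraries that mix the treatments, camera called as many lists as in the real split or more (up to 18). The number of called lists therefore does not by itself separate the treatments. Each mixed split keeps part of their difference, so it cannot show whether the calls are false. Counts of members below are over all genes tested; adjusted over the list alone they were the same for every list but 3, which are named.

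**Figure D3:**
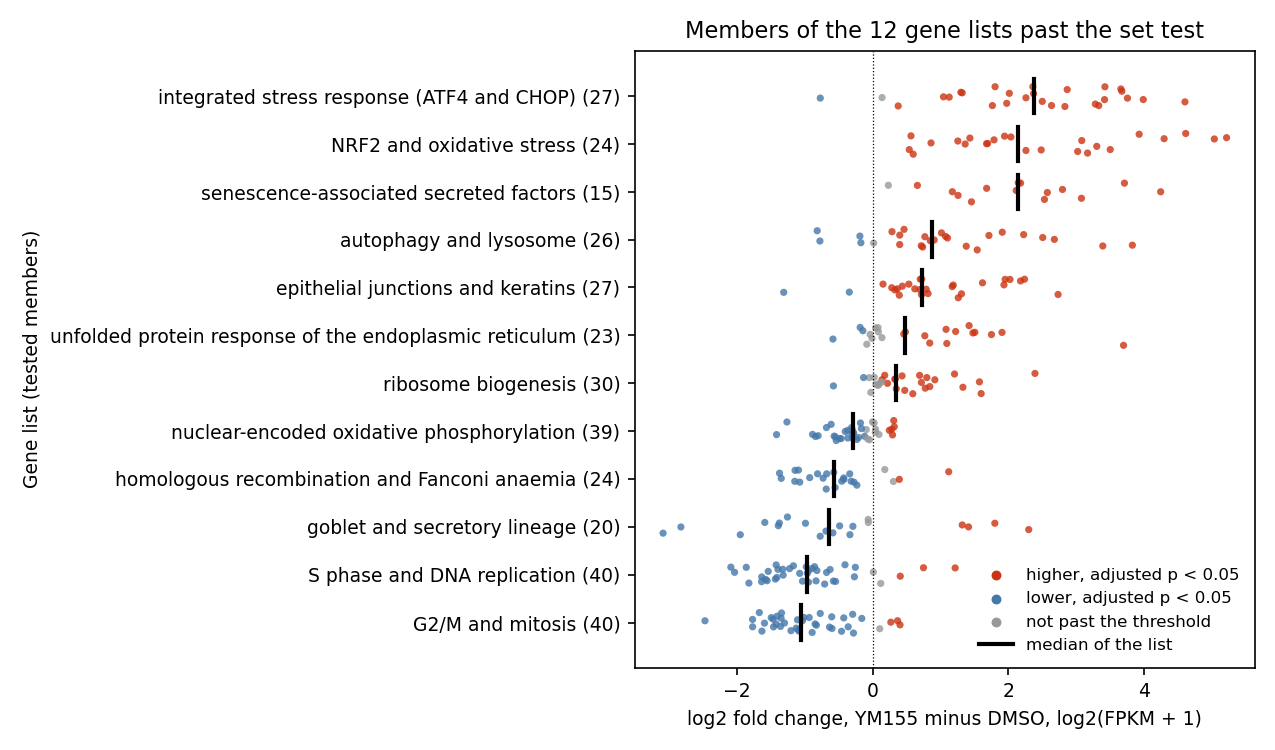
Log2 fold change (YM155 minus DMSO, log2(FPKM + 1) scale) of each tested member of the 12 lists called by camera, with the number of members in brackets. Points are genes (red, higher; blue, lower; grey, not past the threshold) and black bars are list medians, which run from -1.06 for G2/M and mitosis to 2.37 for the integrated stress response.

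Of 40 genes of G2/M and mitosis, 36 fell, 3 rose and 1 did not pass, with the same counts adjusted over the list alone (adjusted p = 2.2e-07 by camera, and adjusted p = 0.33 with an estimated correlation). TOP2A, the topoisomerase of dividing cells, fell from 47.8 ± 2.22 to 13.3 ± 0.835 FPKM, the kinetochore gene CENPF fell 3.96-fold and the spindle gene NUSAP1 2.93-fold. PRC1, of the central spindle, was at 29.5 ± 1.23 FPKM with DMSO and 31.8 ± 0.654 FPKM with YM155 and did not pass (adjusted p = 0.071). Within the chromosomal passenger complex, of which survivin is a subunit, AURKB fell 2.19-fold and INCENP 1.32-fold, while CDCA8 rose 1.31-fold, a call that ended under upper-quartile, quantile and sum scaling. With 3 members lower and 1 higher, the same adjusted over the list alone, that list was not called (adjusted p = 0.24 by camera, and adjusted p = 0.48 with an estimated correlation).

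Of 40 genes of S phase and DNA replication, 35 fell and 3 rose, with the same counts adjusted over the list alone (adjusted p = 2.2e-07 by camera, and adjusted p = 0.29 with an estimated correlation). PCNA, the sliding clamp of DNA polymerases, fell from 92.01 ± 1.83 to 34.4 ± 0.915 FPKM, and UHRF1, of maintenance DNA methylation, fell 5.66-fold. SLBP, the histone stem-loop binding protein gene, was at 31.97 ± 0.579 FPKM with DMSO and 34.9 ± 2.50 FPKM with YM155 (adjusted p = 0.079). The 3 members that rose, named after their values were seen, were CCNE1 (log2 fold change 0.75), CDC6 (1.22) and CDT1 (0.41), which act at the start of replication. Of 24 genes of homologous recombination and the Fanconi anaemia pathway, 20 fell and 2 rose, the same adjusted over the list alone (adjusted p = 0.0033 by camera, and adjusted p = 0.29 with an estimated correlation). BRCA1 fell 3.43-fold, FANCI 2.21-fold and FANCF 2.46-fold, whereas the end-resection gene RBBP8 rose 2.27-fold and RAD54L did not pass (4.71 ± 0.159 FPKM with DMSO and 5.47 ± 0.597 FPKM with YM155).

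Of 7 cyclin-dependent kinase inhibitor genes, 5 rose and 1 fell, the same adjusted over the list alone, and the list was not called (adjusted p = 0.15 by camera, and adjusted p = 0.42 with an estimated correlation). CDKN1A, encoding p21, rose from 8.57 ± 0.0947 to 67.6 ± 2.66 FPKM, CDKN2B rose 6.72-fold, CDKN2D 3.16-fold and CDKN2A 2.49-fold. CDKN2C fell from 1.10 ± 0.0340 to 0.115 ± 0.0629 FPKM, and CDKN1B did not pass (16.8 ± 1.90 FPKM with DMSO and 16.1 ± 0.592 FPKM with YM155). CDKN1C rose 1.25-fold, but its log2 fold change of 0.27 turned to -0.0238 with upper-quartile scaling and -0.00192 with sum scaling (0.26 and 0.27 relative to the median of all genes). Of 29 p53-responsive genes 17 rose and 10 fell, the same adjusted over the list alone (adjusted p = 0.21 by camera, and adjusted p = 0.42 with an estimated correlation). Among them the death receptor gene TNFRSF10B rose from 24.9 ± 0.283 to 189 ± 4.81 FPKM, SFN, encoding 14-3-3 sigma, rose 16.3-fold, and PLK3 rose 8.52-fold. CCNG1 did not pass (78.1 ± 7.33 FPKM with DMSO and 79.6 ± 6.92 FPKM with YM155).

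Of 27 genes of the integrated stress response, which are induced by ATF4 and CHOP, 25 rose and 1 fell, and 26 rose adjusted over the list alone (adjusted p = 1.5e-08 by camera, and adjusted p = 0.18 with an estimated correlation). The list median was a log2 fold change of 2.37. ASNS, encoding asparagine synthetase, rose from 26.9 ± 0.538 to 376 ± 10.9 FPKM, SLC3A2, a subunit of amino acid exchangers, rose 12.8-fold, and AARS, an aminoacyl-tRNA synthetase gene, rose 6.36-fold. ATF5 was at 19.6 ± 1.24 FPKM with DMSO and 21.7 ± 0.805 FPKM with YM155 (adjusted p = 0.0519). The unfolded protein response of the endoplasmic reticulum had 13 of 23 members higher and 3 lower, the same adjusted over the list alone (adjusted p = 0.038 by camera, and adjusted p = 0.48 with an estimated correlation). ERN1, encoding the sensor IRE1, rose 17.7-fold, the chaperone gene HSPA5 rose from 129 ± 6.68 to 486 ± 7.91 FPKM, HERPUD1 rose 3.42-fold and HYOU1 2.87-fold, whereas HSP90B1 did not pass (279.6 ± 12.8 FPKM with DMSO and 288 ± 6.11 FPKM with YM155). The call of this list ended with upper-quartile, sum and quantile scaling, with a mean FPKM of at least 5 and with the abundance trend removed.

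Every one of the 24 tested genes of the NRF2 and oxidative stress list rose, the same adjusted over the list alone (adjusted p = 7.9e-09 by camera, and adjusted p = 0.19 with an estimated correlation), with a median log2 fold change of 2.15. GCLC, the catalytic subunit of glutathione synthesis, rose from 18.4 ± 0.876 to 380.3 ± 13.1 FPKM, the thioredoxin reductase gene TXNRD1 rose 11.5-fold and the aldo-keto reductase gene AKR1B10 8.22-fold. All 5 tested metallothionein genes rose, the same adjusted over the list alone, with MT2A going from 8.01 ± 2.53 to 209 ± 50.8 FPKM and MT1X from 2.24 ± 0.406 to 70.7 ± 18.1 FPKM, and MT1E rising 7.13-fold. MT1F and MT1G were scarcer, at 3.18 and 3.87 FPKM with YM155, and the list as a whole was not called (adjusted p = 0.0502 by camera, and adjusted p = 0.48 with an estimated correlation). Reads of metallothionein genes can be shared between them. Of 17 heat shock and chaperone genes 13 rose and 3 fell, the same adjusted over the list alone (adjusted p = 0.069 by camera, and adjusted p = 0.43 with an estimated correlation). HSF1 rose 2.61-fold, BAG3 2.31-fold and FKBP4 1.96-fold, while HSPB1 fell 2.22-fold and HSP90AA1 did not pass (231 ± 2.99 FPKM with DMSO and 221 ± 1.34 FPKM with YM155).

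Of 26 autophagy and lysosome genes 21 rose and 4 fell, the same adjusted over the list alone (adjusted p = 8.7e-04 by camera, and adjusted p = 0.33 with an estimated correlation). The autophagy receptor gene SQSTM1 rose from 157 ± 5.68 to 1662 ± 77.1 FPKM, the lysosomal cholesterol transporter gene NPC1 rose 15.6-fold, GABARAPL1 6.70-fold and the lysosomal regulator TFE3 6.06-fold, whereas GABARAPL2 did not pass (62.1 ± 5.31 FPKM with DMSO and 62.7 ± 2.73 FPKM with YM155). Of 15 secreted factors associated with senescence 14 rose, the same adjusted over the list alone (adjusted p = 3.7e-05 by camera, and adjusted p = 0.18 with an estimated correlation). GDF15 rose from 98.7 ± 5.52 to 693 ± 50.8 FPKM, VEGFA 5.93-fold, PLAUR 13.5-fold and the EGFR ligand gene EREG 23.02-fold, and CXCL1 did not pass (2.64 ± 1.02 FPKM with DMSO and 3.21 ± 0.724 FPKM with YM155).

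Of 6 tested genes of the inhibitor of apoptosis family, BIRC6 (2.04-fold) and XIAP (2.31-fold) rose, and BIRC5 and NAIP (2.75-fold) fell. BIRC2 was 1.18-fold higher (log2 fold change 0.23, SE 0.06, adjusted p = 0.0064), but its log2 fold change turned to -0.11, -0.0856 and -0.10 with upper-quartile, sum and quantile scaling, or 0.17, 0.19 and -0.0178 relative to the median of all genes. BIRC7 did not pass (2.73 ± 0.613 FPKM with DMSO and 2.14 ± 0.437 FPKM with YM155), and the list, with 3 higher and 2 lower also adjusted over the list alone, was not called (adjusted p = 0.95 by camera, and adjusted p = 0.98 with an estimated correlation). All 4 anti-apoptotic genes tested rose, the same adjusted over the list alone: CFLAR 2.81-fold, BCL2L1 2.31-fold, BCL2L2 2.03-fold and MCL1 1.34-fold (adjusted p = 0.06 by camera, and adjusted p = 0.33 with an estimated correlation). The call of MCL1 ended with upper-quartile, sum and quantile scaling, and its log2 fold change was -0.0114 with the last. Of 10 pro-apoptotic BCL2 family genes 5 rose and 4 fell, the same adjusted over the list alone (adjusted p = 0.8 by camera, and adjusted p = 0.81 with an estimated correlation). PMAIP1 (NOXA) rose 7.01-fold, BBC3 (PUMA) 5.58-fold and BAK1 1.92-fold, BMF fell 6.34-fold, and BOK did not pass (14.4 ± 1.27 FPKM with DMSO and 14.6 ± 1.82 FPKM with YM155). The list of the reported target, its binding proteins and transport held 4 members that rose and 5 that fell, the same adjusted over the list alone (adjusted p = 0.77 by camera, and adjusted p = 0.78 with an estimated correlation), with SP1 2.24-fold and the drug exporter gene ABCC1 1.74-fold higher.

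Of 27 genes of epithelial junctions and keratins 25 rose and 2 fell, the same adjusted over the list alone (adjusted p = 5.2e-05 by camera, and adjusted p = 0.18 with an estimated correlation). KRT20, a keratin of differentiated intestinal epithelium, rose from 120.1 ± 1.36 to 805 ± 51.9 FPKM, the desmosome genes DSP and JUP rose 4.68-fold and 3.90-fold, and TJP1, of tight junctions, rose 4.92-fold. Of 15 TGF-beta, mesenchymal and YAP target genes 12 rose and 3 fell, the same adjusted over the list alone (adjusted p = 0.0502 by camera, and adjusted p = 0.42 with an estimated correlation). PMEPA1 rose 3.04-fold, whereas CTGF, a YAP target, fell 4.13-fold.

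Of 20 genes of the goblet and secretory lineage 14 fell and 4 rose, the same adjusted over the list alone (adjusted p = 0.041 by camera, and adjusted p = 0.51 with an estimated correlation). SPINK4 fell from 469 ± 15.9 to 54.5 ± 7.60 FPKM, the trefoil factor gene TFF3 from 78.2 ± 5.56 to 19.5 ± 1.38 FPKM and SPINK1 2.63-fold, whereas KLF4 rose 5.18-fold and CREB3L1 did not pass (64.3 ± 2.97 FPKM with DMSO and 61.5 ± 4.33 FPKM with YM155). The call ended with upper-quartile and sum scaling and without a filter. Of 10 intestinal stem cell and progenitor genes 6 fell and 2 rose, the same adjusted over the list alone (adjusted p = 0.12 by camera, and adjusted p = 0.39 with an estimated correlation). PROM1 fell from 18.3 ± 0.481 to 1.93 ± 0.311 FPKM, LGR5 from 6.94 ± 0.451 to 0.857 ± 0.118 FPKM, ALDH1A1 1.87-fold and CD44 1.68-fold, and SOX9 did not pass (22.6 ± 1.03 FPKM with DMSO and 24.1 ± 1.02 FPKM with YM155).

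Of 39 nuclear genes of oxidative phosphorylation 26 fell and 5 rose, the same adjusted over the list alone (adjusted p = 0.005 by camera, and adjusted p = 0.51 with an estimated correlation). NDUFB10, of complex I, fell from 104 ± 4.72 to 42.8 ± 0.610 FPKM, NDUFA8 fell 2.74-fold, NDUFB3 1.81-fold and NDUFV2 1.61-fold, and COX6A1 did not pass (585 ± 39.3 FPKM with DMSO and 602 ± 26.5 FPKM with YM155). Of 30 ribosome biogenesis genes 20 rose and 2 fell, or 20 and 1 adjusted over the list alone (adjusted p = 0.005 by camera, and adjusted p = 0.19 with an estimated correlation). RRP9 rose 5.47-fold, the RNA helicase gene DDX21 from 58.4 ± 0.861 to 179 ± 8.63 FPKM, RRP12 3.14-fold and NOP2 2.57-fold, and FBL did not pass (301 ± 12.6 FPKM with DMSO and 319 ± 17.6 FPKM with YM155). This call ended with upper-quartile, sum and quantile scaling, with a mean FPKM of at least 5 and with the abundance trend removed. Of 46 cytosolic ribosomal protein genes 9 rose and 7 fell, or 6 and 5 adjusted over the list alone, and the list was not called (adjusted p = 0.95 by camera, and adjusted p = 0.98 with an estimated correlation). Its median log2 fold change of 0.04 and mean of 0.0016 were positive and its test negative, and it was called lower with upper-quartile, sum and quantile scaling and with the abundance trend removed.

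In the other 17 lists, none of them called by camera, counts were the same adjusted over the list alone, and the adjusted p in brackets is that of camera. Of 13 death receptor genes 6 rose and 5 fell (adjusted p = 0.56), and 15 of 25 cholesterol synthesis genes rose and 9 fell (adjusted p = 0.36). Of 10 fatty acid synthesis genes 6 rose and 2 fell (adjusted p = 0.21), and 10 of 19 glycolysis genes rose and 6 fell (adjusted p = 0.35). Of 17 hypoxia response genes 9 rose and 5 fell (adjusted p = 0.36), and 6 of 14 mitochondrial DNA maintenance genes rose and 7 fell (adjusted p = 0.63). Of 26 proteasome genes 13 rose and 3 fell (adjusted p = 0.15), and 2 of 8 replication-dependent histone genes rose and 3 fell (adjusted p = 0.8). Of 18 MYC target genes 12 rose and 5 fell (adjusted p = 0.36), and 13 of 23 immediate early and AP-1 genes rose and 8 fell (adjusted p = 0.24). Of 15 ERK feedback genes 8 rose and 6 fell (adjusted p = 0.47), and 11 of 17 NF-kB and cytokine genes rose and 2 fell (adjusted p = 0.062). Of 24 interferon-stimulated genes 15 rose and 4 fell (adjusted p = 0.15), and 9 of 13 antigen presentation genes rose and 2 fell (adjusted p = 0.15). Of 16 Wnt target genes 4 rose and 8 fell (adjusted p = 0.36), and 8 of 16 absorptive enterocyte genes rose and 7 fell (adjusted p = 0.61). Of 8 EGFR ligand and receptor genes 5 rose and 3 fell (adjusted p = 0.36). With an estimated correlation their adjusted p values were 0.39 to 0.81. Direction of list medians turned with upper-quartile and sum scaling for the death receptor, cholesterol, glycolysis, hypoxia, proteasome, MYC, ERK and absorptive enterocyte lists, which follows the shift of all genes, as these medians stayed 0.0911 to 0.26 above the median of all genes. The cholesterol, glycolysis, hypoxia, MYC and proteasome medians also turned with quantile normalization. There they lay at -0.22 to -0.0209 relative to the median of all genes, so its shift alone does not account for that turn. The absorptive enterocyte median turned as well, but at 0.0522 relative to it. Of members chosen after their values were seen, EGFR rose from 5.15 ± 0.348 to 33.6 ± 2.33 FPKM and AREG, an EGFR ligand gene, from 3.37 ± 0.656 to 24.8 ± 0.470 FPKM, whereas ERBB2 fell 2.06-fold and ERBB3 1.97-fold.

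Lists with fewer than 4 tested members were not tested. Mitochondrially encoded genes were not analysed here. Of the enteroendocrine genes, NEUROG3 fell from 6.77 ± 0.493 to 1.01 ± 0.382 FPKM and ISL1 from 2.18 ± 0.350 to 1.25 ± 0.132 FPKM. Markers of other cell types were near 0: no fibroblast marker was tested, and COL1A1 averaged 0.303 FPKM with DMSO and 0.111 FPKM with YM155. PTPRC, the pan-leukocyte marker, averaged 0.00574 and 0.00451 FPKM, and the endothelial marker PECAM1 0.0523 and 0.146 FPKM. Of the leukocyte list, the lysosomal protein gene CD68 rose from 4.85 ± 0.921 to 82.9 ± 4.51 FPKM and CD79A from 0.399 ± 0.0154 to 4.85 ± 0.729 FPKM, and LYZ did not pass (1956 ± 135 FPKM with DMSO and 2004 ± 72.6 FPKM with YM155). ESAM, of the endothelial list, rose from 16.6 ± 0.965 to 63.3 ± 3.09 FPKM.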

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

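Leaving out small RNA rows and removing the abundance trend were chosen after seeing the data, and the other settings before the data were examined. Of 129 genes followed through the settings, 113 passed the threshold. Of these, 3 changed sign in some setting (BIRC2, MCL1 and CDKN1C) and MCL1 and CDCA8 lost their call while keeping their sign. BIRC5 kept its direction and call in every setting, with log2 fold changes from -1.99 (common sum) to -1.59 (without YM155 replicate 3). Of the genes that did not pass, 14 changed sign in some setting. All 16 of them passed in some setting, 8 with their sign kept and 10 with it changed, ATF5 and SLBP counting in both. Leaving out 1 library let 5 of them pass: BIRC7 and ATF5 without DMSO replicate 3, CXCL1 without DMSO replicate 1, RAD54L and ATF5 without YM155 replicate 2, and SLBP without YM155 replicate 3. The metallothionein list then passed without DMSO replicate 1 or 2 or YM155 replicate 1 or 2, and the TGF-beta list without DMSO replicate 2 or YM155 replicate 2. The number of genes lower was 2922 with a mean FPKM of at least 5, where fewer genes were tested, and 771 then had a log2 fold change of at most -1. A log2 fold change of at most -1 was seen for 2155 genes with a pseudocount of 0.1, 2401 with upper-quartile scaling and 2666 with a common sum, and of at least 1 for 1179 with upper-quartile scaling; the cause was not tested. Lists called higher numbered 13 without a filter, and 0 higher and 0 lower with camera's estimated correlation (7 at an unadjusted p under 0.05). All 12 called lists passed with every library left out in turn, and 9 passed with upper-quartile and sum scaling.

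The replicate numbers did not pair the libraries: deviations of same-numbered libraries from their group means correlated at -0.07, -0.15 and -0.12, and no library correlated best with its own number. With a replicate block 5147 genes were higher and 4861 lower, and all 12 called lists passed.

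The sign changes below are log2 fold changes, and their cause was not tested beyond the shift of the median of all genes given with the scalings. With upper-quartile scaling, the sign turned for the genes BIRC2 -0.11, BOK -0.31, CCNG1 -0.32, PRC1 -0.23, SLBP -0.22, RAD54L -0.11, CDKN1C -0.0238, ATF5 -0.20, HSP90B1 -0.30, COX6A1 -0.31, FBL -0.26, SOX9 -0.25, GABARAPL2 -0.33 and CXCL1 -0.0267. For lists the medians that turned were then pro-apoptotic BCL2 family -0.21, death receptor -0.17, cholesterol synthesis -0.0366, glycolysis -0.18, hypoxia response -0.13, cytosolic ribosomal proteins -0.31, MYC target -0.14, ERK feedback -0.10, absorptive enterocyte -0.11 and proteasome -0.19. With rescaling to a common sum, the sign turned for the genes BIRC2 -0.0856, BOK -0.29, CCNG1 -0.29, PRC1 -0.21, SLBP -0.20, RAD54L -0.0978, CDKN1C -0.00192, ATF5 -0.17, HSP90B1 -0.28, COX6A1 -0.28, FBL -0.24, SOX9 -0.23, GABARAPL2 -0.31 and CXCL1 -0.00528. For lists the medians that turned were then pro-apoptotic BCL2 family -0.19, death receptor -0.15, cholesterol synthesis -0.0111, glycolysis -0.16, hypoxia response -0.11, cytosolic ribosomal proteins -0.28, MYC target -0.12, ERK feedback -0.0787, absorptive enterocyte -0.0854 and proteasome -0.17. With quantile normalization, the sign turned for the genes BIRC2 -0.10, BIRC7 0.0313, MCL1 -0.0114, BOK -0.21, CCNG1 -0.41, PRC1 -0.26, SLBP -0.25, ATF5 -0.15, HSP90B1 -0.46, COX6A1 -0.43, FBL -0.42, SOX9 -0.23 and GABARAPL2 -0.43. For lists the medians that turned were then pro-apoptotic BCL2 family -0.21, cholesterol synthesis -0.14, glycolysis -0.18, hypoxia response -0.10, cytosolic ribosomal proteins -0.17, MYC target -0.13, absorptive enterocyte -0.0307 and proteasome -0.31. With the abundance trend removed, the sign turned for the genes BIRC2 -0.0864, BIRC7 0.0980, BOK -0.19, CCNG1 -0.32, PRC1 -0.22, SLBP -0.21, ATF5 -0.14, HSP90B1 -0.26, COX6A1 -0.20, FBL -0.21, SOX9 -0.22 and GABARAPL2 -0.33. For lists the medians that turned were then inhibitor of apoptosis family 0.00581, pro-apoptotic BCL2 family -0.16, cholesterol synthesis -0.0364, glycolysis -0.11, hypoxia response -0.0587, cytosolic ribosomal proteins -0.13, MYC target -0.0578 and proteasome -0.16. With median-of-ratios scaling, the sign turned for the genes BOK -0.0164, CCNG1 -0.00885 and GABARAPL2 -0.0218. With array quality weights, the sign turned for the genes BOK -0.00509 and GABARAPL2 -0.00525. For lists the medians that turned were then inhibitor of apoptosis family 0.0212. With a mean FPKM of at least 5, the list medians that turned were inhibitor of apoptosis family 0.60 and Wnt target 0.0852. Without a filter, the list medians that turned were inhibitor of apoptosis family 0.23, Wnt target 0.00856 and replication-dependent histone 0.00141. Leaving out single libraries turned the sign of BOK (-0.0758 to 0.0747), CCNG1 (-0.0490 to 0.10), CDKN1B (-0.12 to 0.0289) and GABARAPL2 (-0.0201 to 0.0832), and of the medians of the ribosomal protein list (-0.00849 to 0.0702) and the inhibitor of apoptosis list (-0.0666 to 0.0341). None of these had passed the threshold. Lower read depth limits what can be said of scarce transcripts in the YM155 libraries.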

Other observations

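Of the tests in this part, those of read depth, of the MTRNR2L rows and of the HOX clusters were chosen only after the results they measure were seen. Genes and families here were chosen after their values were seen, except the members of the hemidesmosome test and of the ciliary test. Among 183 families of genes that share a symbol stem, tested with camera and its preset correlation, the keratins were the only family called higher, with 12 of 12 tested KRT genes higher (adjusted p = 0.0041, and adjusted p = 0.58 with an estimated correlation), among them KRT80 (from 8.78 ± 0.365 to 166 ± 20.8 FPKM) and KRT15 (from 1.98 ± 0.374 to 13.1 ± 0.857 FPKM). Genes of epithelial laminin rose with them: LAMA3 from 6.11 ± 0.162 to 133 ± 6.36 FPKM and LAMB3 12.6-fold. The hypothesis that the hemidesmosome, which binds that laminin and anchors epithelium to the basement membrane, rose too was tested on 6 of its genes without the laminin genes, whose values had been seen. All 6 were higher, and their median log2 fold change of 1.65 lay at percentile 99.69 of 10000 random lists matched on level. Because random lists draw single genes, this percentile and those below treat genes as independent and do not measure the spread between libraries. Of the 6, ITGB4 went from 86.6 ± 2.94 to 321 ± 20.6 FPKM and PLEC from 31.6 ± 1.65 to 216 ± 16.2 FPKM.

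Lower families were IFT, HOXA, HOXB, MCM, NDUFB, NDUFA and MRPL (adjusted p from 0.0025 to 0.046). With an estimated correlation camera called 0 of the 183 families (lowest adjusted p = 0.58, and 6 at an unadjusted p under 0.05). The family calls therefore held only with the preset setting. Why they were lost was not tested, and the loss by itself does not show that correlation between genes accounts for the calls. Of the IFT genes of intraflagellar transport 14 of 14 fell, with IFT81 going from 10.6 ± 1.12 to 1.91 ± 0.270 FPKM and IFT80 from 9.97 ± 0.501 to 2.60 ± 0.0414 FPKM. The hypothesis that other ciliary genes fell too was tested on 30 of them: 22 fell and 6 rose, with a median of -0.83 at percentile 0.3. These 30 include BBS genes, a family in the scan that gave the IFT result (5 of 8 fell and 3 rose). The ciliary test is therefore not fully separate from that scan. The HOXA family test took 14 rows, of which 13 fell, and of the 11 HOXA genes proper, with antisense and readthrough rows left out, 10 fell, such as HOXA10 (from 35.4 ± 1.45 to 10.9 ± 0.659 FPKM) and HOXA3 (from 16.2 ± 0.177 to 3.77 ± 0.369 FPKM). In the other HOX clusters 11 of 14 genes fell, with a median of -1.13 at percentile 0 of the random lists, such as HOXB5 (from 36.9 ± 1.81 to 6.82 ± 0.980 FPKM) and HOXC6 (from 12.6 ± 0.506 to 1.38 ± 0.197 FPKM), and HOXB7 fell less (log2 fold change -0.22). The 14 genes include those of HOXB, already called as a family, and HOXC and HOXD were not tested apart from them. A fall shared by the clusters is a hypothesis that these values leave open. Long non-coding RNAs were also lower: 292 of 492 fell and 126 rose, with a median of -0.48, against -0.32 in lists of coding genes matched on level.

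On the deposited scale scarce transcripts were lower and abundant ones higher with YM155, with a Spearman rho of 0.31 between the log2 fold change and the mean level across genes, which are not independent. After upper-quartile and sum scaling, the most abundant decile had medians of -0.0878 and -0.0618 and the scarcest -0.73 and -0.88, so a rise of abundant transcripts depended on the scale. Those scalings use 1 factor per library and could hardly change the difference between scarce and abundant transcripts (rho of 0.26 and 0.29), whereas quantile normalization, which makes the distributions equal, left a rho of 0.0171. Read depth alone would leave the summed FPKM of scarce genes equal, but the scarcest decile had a ratio of YM155 to DMSO of 0.649 (0.642 to 0.660 over pairs of libraries). Background from genomic DNA would show in genes the cells should not express: olfactory receptor rows averaged at most 0.0289 FPKM in a DMSO library, against 0.550 FPKM lost by the scarcest decile. The shift was not limited to non-coding rows, since coding genes of that decile had a median of -0.56. The change also followed genomic length (Spearman rho of 0.16), with medians of -0.19 in the shortest decile and 0.30 in the longest, and this was not separated from abundance. Among what stays open for this trend are a bias with gene length and a library step that differed between the groups. FPKM cannot show a change in the amount of RNA per cell. If equal for all genes, such a change would act as 1 factor per library. A single factor per library could hardly change rho in any data, so the rho of 0.26 and 0.29 left by such scalings is no test of it. By the same reasoning, such a factor could hardly give the trend.

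MTRNR2L2, MTRNR2L8 and MTRNR2L9, nuclear genes that resemble mitochondrial ribosomal RNA, rose 6.18-fold, 5.79-fold and 6.11-fold, the last from 628 ± 18.4 to 3834 ± 171 FPKM. Their log2 fold changes lay closer together than those of most of 10000 random triples of risen genes (1.82% spanned no more). Reads of a single source shared between the rows would give this. The comparison was chosen after the folds were seen, so it cannot test that. The other 2 tested rows of this kind, MTRNR2L1 and MTRNR2L6, both under 5 FPKM and left out of that comparison, rose 5.81-fold and 3.64-fold. A rise of all mitochondrial RNA stays open: the only row used to test it was MIR6723, a small RNA row within a nuclear copy of a mitochondrial protein gene, which was lower (log2 fold change -0.45, SE 0.14, adjusted p = 0.016) but is 1 row of a class that FPKM measures poorly, with overlapping groups. Whether the source is mitochondrial ribosomal RNA was not tested.

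The 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 10191 genes past the threshold and the highest other split 3, so 1 of the 10 splits gave as many. With a log2 fold change of at least 1 in size the values were 3334 and 3, again 1 of 10. For lists called by camera the real split gave 12 and the highest other 18, and 8 of the 10 splits gave as many. Since each other split mixes the treatments, it keeps part of their difference.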
